A study of Sus scrofa with 20 samples.

How the data were processed

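Messenger RNA of the hypothalamus was sequenced from 20 pigs as paired reads of 76 bases. Per the labels' protocols, tissue was snap-frozen after death, total RNA had integrity numbers of 7.8 to 9.8, and libraries were made with an Illumina messenger RNA kit for which the labels state no strand marking. Per the submitters' processing notes, the tools were FastQC, Trim Galore, HISAT2, HTSeq and DESeq2 with the genome build Sscrofa11.1; no versions, annotation release, strand setting or overlap mode are given in the sources used here. The deposited values are raw counts per gene with 1 column per animal and no normalization, and they hold 25880 gene rows and 5 summary lines. The summary lines were left out of library sizes and tests, and their shares of all entries were 80.2 to 88.1% for no feature, 3.89 to 9.50% for alignments that were not unique, 2.73 to 5.92% for low alignment quality, 0.548 to 0.665% for reads not aligned and 0.0864 to 0.121% for ambiguous entries.

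Gene identifiers were matched to symbols in a reference table, which named 14857 identifiers (57.4%). Coordinates came from RefSeq genes of Sscrofa11.1 by unique symbol, for 5576 of the tested genes. That table gives no strand, so overlapping and adjoining genes are described by position only. Strand marking changes which of 2 overlapping genes receives a read, and counts of such genes can move between them.

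Counts per gene were tested with edgeR 4.0.16 in R 4.3.3 after TMM scaling and a filter by expected counts (minimum 10 in a group-sized number of libraries, 15 in all), which kept 7090 genes, 5996 of them with a symbol. A quasi-likelihood model with 1 mean for each of the 4 groups was fitted to all 20 libraries with robust dispersions (common biological coefficient of variation 0.176). The 7 contrasts were breed, breed in females, breed in males, sex, sex in Iberian, sex in crossbred and the interaction, each as crossbred minus Iberian or male minus female, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors are those of the log2 fold change. Values in CPM (counts scaled to library size) are given as mean and SD. A gene at 0 in every library of a group was compared with a floor of 3 counts over that group, and such floors cover counting error only.

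The study design and the rule for named genes were fixed before the data were examined. For breed, the rule took up to 8 rising and 8 falling genes by fold among called genes with a symbol and a mean CPM of at least 1 in a group, up to 3 called members per list, and 16 fixed hypothalamic genes. For sex it took up to 6 and 6, up to 2 called members per list, XIST and the measured Y-linked genes, for the contrasts within 1 group up to 3 and 3, and for the interaction up to 6 called genes. Where no gene was called, the 5 with the smallest p were named. In all, 37 gene lists were fixed with 870 entries, and 28 with at least 4 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it. Each list's breed result is given in the report.

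Alternatives were RLE size factors, DESeq2 1.42.0, limma voom with quality weights, no filter, a filter at 1 CPM in 5 libraries, the replicate number as a block, 2 surrogate variables from sva 3.50.0, no robust estimation, an additive model, only the groups compared, and each library left out in turn. After the data had been seen, a term for the share of low-quality alignments (above or below 4.5%), the same term without Iberian male replicate 5, and fits within the high-share or low-share libraries were added. Pairs of libraries within a group were compared for duplicates over genes with at least 20 counts in the pair, and the chi-square per degree of freedom ran from 2.45 to 73.8 over 40 pairs, so none was a repeat within sampling noise.

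The test was tried on simulated counts with 200 of 7090 genes changed. For the breed contrast 64% of genes changed 1.5-fold and 93% changed 2-fold were recovered. For breed in females the shares were 23% and 51%, for breed in males 19% and 57%, for sex 49% and 89%, for sex in Iberian 16% and 60%, for sex in crossbred 19% and 55%, and for the interaction 2% and 26%. No recovered gene had the wrong sign. A myelin list shifted by 0.5 on the log2 scale was recovered and 0 other lists were called. Genes were drawn independently there, so this does not test how often lists are falsely called when their members vary together.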

Results

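RNA of the hypothalamus, the brain region that governs feeding, growth and reproduction through its peptides, was sequenced from 20 pigs at 2 months of age. The series compared pure Iberian pigs, a breed known for its fat deposition, with crosses of Iberian and Large White, a lean breed. Each breed held 5 females and 5 males, so that 4 groups of 5 libraries were available, each library from 1 animal. The series design names breed and sex as its factors, and the questions asked here were which transcripts differed between breeds, between sexes, and between breeds in a manner that depended on sex.

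Counts assigned to genes came to between 1430138 and 2384615 per library, which was 4.04 to 4.62% of the 32925841 to 57277346 entries counted for each library. Entries that matched no annotated feature took 80.2 to 88.1%. In 20 of 20 libraries ND6, the only mitochondrial messenger copied from the other strand, had the most counts of the 13 mitochondrial messengers, with 5.37 to 23.7% of all gene counts against 0.141 to 0.292% for COX1. The upper limit for ND6 was that of Iberian male replicate 5 alone, and its share over all libraries was 8.15%. The names below therefore stand for the identifier to which counts were assigned. Whether those counts came from the messenger or from the opposite strand is uncertain for every gene and gene list below. Genes that overlap or adjoin another gene may also share counts with it. The strand setting of the counting is not given in the sources used here. Within the small share of entries assigned to genes, many hypothalamic peptides were barely counted. ND6 had 19.8 to 141 times the counts of COX1 over the 20 libraries, which argues against counts that followed the messengers. Low counts of these peptides therefore cannot be read as low expression, and their expression was not settled. The leptin receptor LEPR had 5 counts over all 20 libraries, the feeding peptide AGRP 23, the satiety peptide CARTPT 41, CRH 7, GHRH 14 and GNRH1 15, and none of these was tested. NPY had 1 to 15 counts per library, PMCH 0 to 16, SST 0 to 6 and OXT 0 to 17, also below the filter. POMC, MC4R, TRH and KISS1 had no identifier matched by symbol and were not analysed here.

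Sex-limited transcripts followed the labelled sex. ENSSSCG00000012178 had 32 to 65 counts in each of the 10 males and 0 in each of the 10 females, and ENSSSCG00000032435 had 68 to 139 counts in each of the 10 females and 0 in each of the 10 males. One Iberian male, replicate 5, stood apart on the first principal component, which held 19.9% of the variance, at 63.95 against -9.40 to 1.19 for the other libraries. That library held 157 counts of PRL (prolactin), 163 of CGA (the alpha chain shared by pituitary glycoprotein hormones) and 111 of FSHB, against at most 4, 2 and 2 in any other library. The share of low-quality alignments split the libraries into a high set and a low set that partly followed breed. It was 5.33 to 5.92% in all 5 Iberian females and in Iberian males 2 and 3, and 2.73 to 3.88% in Iberian males 1, 4 and 5 and in all 10 crossbred animals. Only Iberian males held libraries of both sets, so a term for this split was estimated from that group alone.

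**Figure D1:**
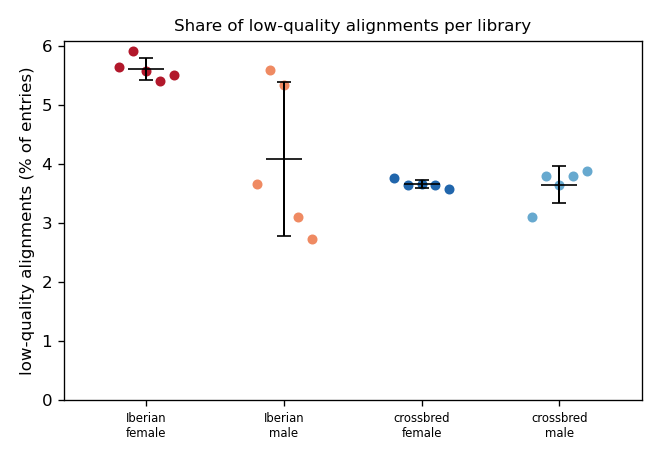
Share of low-quality alignments (percent of entries, y axis) in each library of the 4 groups (x axis), with the group mean and SD as a bar. The 7 libraries above 5% are all Iberian, and the 13 others lie between 2.73 and 3.88%.

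Between breeds, 16 of 7090 tested genes passed the threshold, 13 higher and 3 lower in crossbred animals. The largest rises with a gene name were for GYPC, the red-cell membrane protein glycophorin C (ENSSSCG00000040701), SGCA, a sarcoglycan of the dystrophin complex (ENSSSCG00000017583), and TBCD, a cofactor for tubulin folding (ENSSSCG00000017136). GYPC measured 12.5 ± 6.24 CPM (counts scaled to library size) in crossbred and 4.56 ± 1.65 in Iberian animals (SD, n = 10 each), a 2.70-fold difference (log2 1.43, SE 0.30, edgeR adjusted p = 0.0344), with 8 of 10 crossbred animals above the Iberian median. SGCA measured 70.0 ± 23.0 against 29.6 ± 13.4, 2.33-fold (log2 1.22, SE 0.24, edgeR adjusted p = 0.0356), with 10 of 10 crossbred animals above the Iberian median. TBCD measured 40.0 ± 10.5 against 19.4 ± 3.61, 2.09-fold (log2 1.06, SE 0.15, edgeR adjusted p = 4.2e-04), with 9 of 10 above. CRISP1, a cysteine-rich secretory protein (ENSSSCG00000001739), was lower in crossbred animals, at 4.05 ± 2.42 against 9.24 ± 3.33 (log2 -1.36, SE 0.27, edgeR adjusted p = 0.0183), with 10 of 10 crossbred animals below the Iberian median.

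Further genes were higher in crossbred animals by smaller amounts. SEPTIN1, a septin of the cytoskeleton, had a log2 difference of 0.85, DUT, the enzyme that removes dUTP, 0.82, and WDR45B, an autophagy protein, 0.68. CCN1, a secreted matrix protein, had 0.58, and TMEM138, a membrane protein of cilia, had 0.57. Their edgeR adjusted p ran from 0.0144 to 0.0490. FHIP2B and the scaffold protein PDZK1 were lower, by log2 values of -0.94 and -0.42 with edgeR adjusted p of 0.0344 and 0.0183. The 5 remaining called identifiers fell outside the rule for named genes and were singled out after their values were seen. They were the glycine transporter SLC6A9 (log2 0.42), the RNA 3' end processing factor CPSF7 (0.40), TDRP (0.38), TMEM120B (0.31) and the unnamed ENSSSCG00000008677 (0.77). Of the fixed hypothalamic genes with enough counts, vasopressin (AVP) had a log2 difference of -0.44 (SE 0.51, edgeR adjusted p = 0.882) and orexin (HCRT) 0.25 (SE 0.22, edgeR adjusted p = 0.838), so neither differed beyond the spread between animals. The value of AVP ran from -0.19 to -0.66 when 1 library was left out. With the split by low-quality alignments as a term, estimated from Iberian males alone, it was -1.65 (SE 0.85, edgeR adjusted p = 0.475).

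On Sscrofa11.1, TBCD spans 327009 to 449375 and WDR45B 522762 to 547333 of chromosome 12. CPSF7 spans 10087581 to 10112929 and TMEM138 10134866 to 10143049 of chromosome 2, and PDZK1 lies at 99625085 to 99657170 of chromosome 4. In the same annotation ZNF750 overlaps TBCD, SDHAF2 and TMEM216 overlap CPSF7, CCDC24 overlaps SLC6A9, RHOF overlaps TMEM120B and GHDC overlaps HCRT. DUT, TMEM138, PDZK1 and AVP each overlap a locus without a gene symbol. All these counts may be shared with the neighbour and are uncertain, and SEPTIN1, CCN1, FHIP2B and ENSSSCG00000008677 had no position to check.

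**Figure D2:**
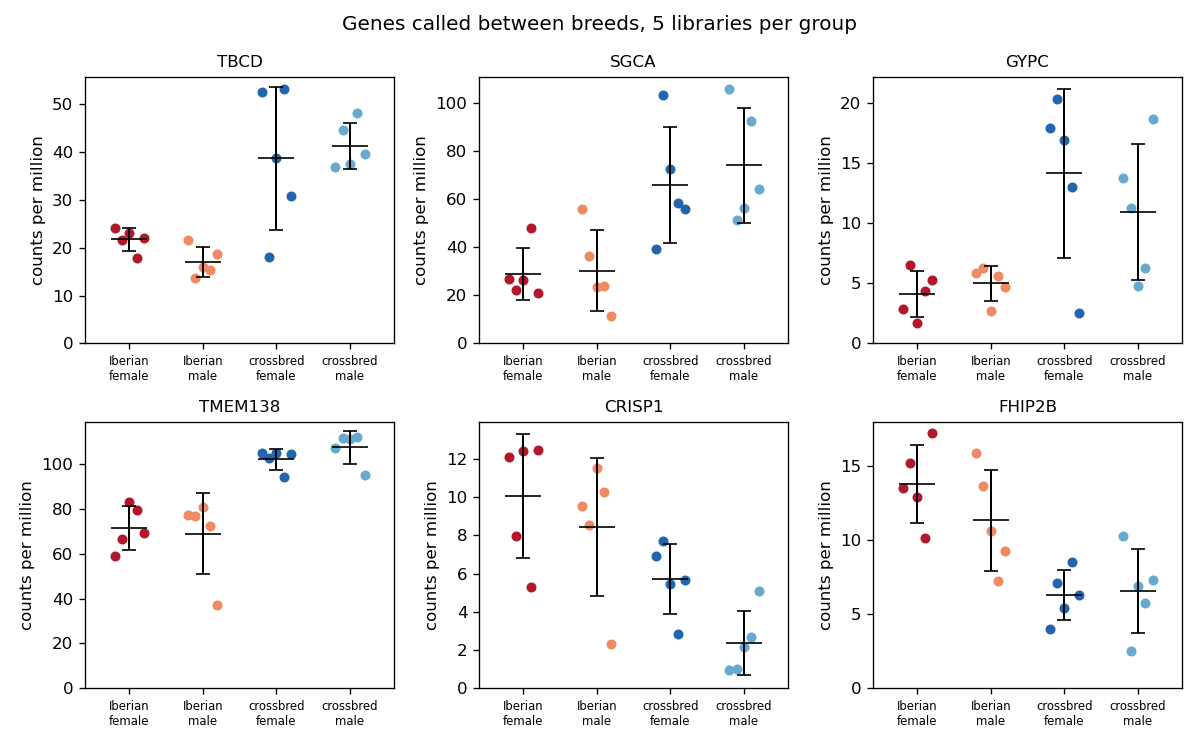
CPM (y axis, from 0) of 6 genes called between breeds, each point 1 library, with the group mean and SD as a bar, for the 4 groups on the x axis. TBCD, SGCA, GYPC and TMEM138 are higher in crossbred animals, and CRISP1 and FHIP2B are lower; the lowest Iberian male for TMEM138 and CRISP1 is replicate 5.

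Among gene groups, the counts assigned to the 13 mitochondrially encoded messengers were lower in crossbred animals, with 13 of 13 fitted values below 0 and a median log2 difference of -0.28. ND2 (-0.38, SE 0.11), ATP6 (-0.28, SE 0.07) and COX1 (-0.25, SE 0.10) were examples. With ND6 at 19.8 to 141 times COX1, whether these counts came from the messengers or from the opposite strand is uncertain. No member passed over all genes tested, and 11 were lower when adjusted over the list alone. The camera test with a preset correlation called the group (adjusted p = 2.74e-11), while its estimated correlation between members was 0.56 and the adjusted p was 0.213 with an estimated correlation. Genes of fatty acid synthesis were higher, with 13 of 13 fitted values above 0 and a median of 0.16; ELOVL7 (0.33, SE 0.14), FADS2 (0.23, SE 0.12) and FASN (0.15, SE 0.11) were examples. No fatty acid synthesis gene passed over all genes or over the list alone, and camera gave an adjusted p of 0.0107, against an adjusted p of 0.173 with an estimated correlation and 0.158 with 2 surrogate variables. The rotation test fry gave adjusted p values of 0.102 for the mitochondrial group and 0.0443 for fatty acid synthesis. In the cholesterol synthesis group 7 of 14 tested genes were above 0 and 7 below, and the group did not pass (adjusted p = 0.539). Its LSS (0.82, SE 0.19) and SREBF2 (0.31, SE 0.11) were higher when adjusted over the list alone and did not pass over all genes.

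**Figure D3:**
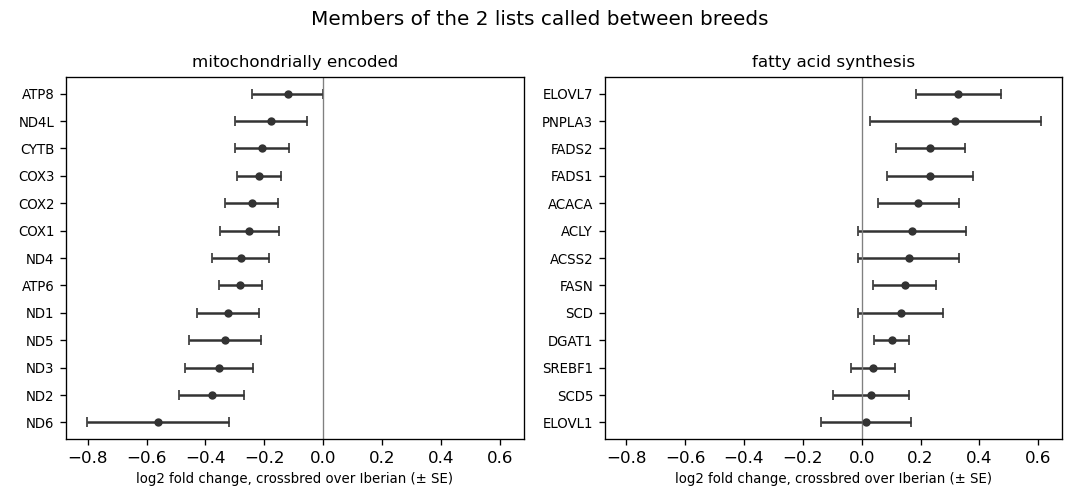
Fitted log2 fold change of crossbred over Iberian animals (x axis) with its SE for each tested member (y axis) of the mitochondrially encoded and fatty acid synthesis lists. All 13 mitochondrial values lie below 0 and all 13 fatty acid synthesis values lie above 0.

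The other 25 gene groups tested as sets did not pass. Hypoxia genes had 6 of 8 fitted values below 0 (adjusted p = 0.0522), myelin and oligodendrocyte genes 13 of 18 above 0 (0.260), tanycyte and ependymal genes 6 of 8 below 0 (0.323), circadian clock genes 9 of 14 below 0 (0.343) and interferon response genes 10 of 12 below 0 (0.343). The adjusted p was 0.539 for monoamine, thyroid hormone, neuron and X escape genes, and 0.688 for growth axis and astrocyte genes. It was 0.764 for glucocorticoid response and 0.781 for antigen presentation. It was 0.917 for the orexigenic, anorexigenic, insulin and leptin signalling, nuclear respiratory chain, heat shock, oligodendrocyte precursor, thalamus and hypothalamic nuclei lists. Microglia and vessel genes had 0.996, and fatty acid oxidation and cytosolic ribosome genes 0.998. Among them ANKRD37 of the hypoxia list (-0.44), SLA-DQB1 of antigen presentation (-0.66) and PTPRZ1 of the precursor list (-0.42) passed when adjusted over the list alone and not over all genes. The signs of median, mean and test did not match for the fatty acid oxidation, precursor, astrocyte, vessel, thalamus and hypothalamic nuclei lists. Another 9 lists had under 4 tested members and were not tested as sets. These were releasing hormones (1 of 2 fitted values above 0), reproductive axis (1 of 3), immediate early genes (1 of 2), inflammation (1 of 3), choroid plexus (1 of 1), anterior pituitary (0 of 1), cortex, hippocampus and striatum (1 of 3) and blood (0 of 1). The Y-linked list had no tested member.

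The breed calls depended on which libraries and terms were in the fit. Leaving out 1 library gave 2 calls without crossbred female replicate 4, 4 without Iberian female replicate 5 and 5 without Iberian female replicate 3. Of 20 such fits, GYPC lost its call in 16, SGCA in 15, SEPTIN1 in 12, FHIP2B in 15, TMEM120B in 16, and WDR45B, TDRP and ENSSSCG00000008677 in 17 each. DUT lost it in 8, CPSF7 in 6, CRISP1 and PDZK1 in 3 each, CCN1 and SLC6A9 in 1 each, and TBCD and TMEM138 in 0. GYPC and SEPTIN1 also lost their call with limma voom, SGCA, TMEM120B and ENSSSCG00000008677 with the filter at 1 CPM in 5 libraries, and TDRP with RLE size factors. WDR45B, TMEM120B and TDRP lost it with the replicate number as a block and without robust estimation. Without Iberian male replicate 5 there were 23 calls, 14 of them shared with the full set, and the fatty acid synthesis list had an adjusted p of 0.0550. SGCA and GYPC lost their call (edgeR adjusted p of 0.0589 and 0.0603), with log2 differences of 1.14 and 1.43 against 1.22 and 1.43 in the full set. ENSSSCG00000008677 then had 0.67 (SE 0.08, edgeR adjusted p = 2.02e-06). It had 0.84 (SE 0.15, edgeR adjusted p = 0.0224) when the split by low-quality alignments was a term as well. With the split by low-quality alignments as a term there were 0 calls with edgeR, while 15 of the 16 genes had an unadjusted p under 0.05 and SLC6A9 had 0.141. These 16 genes had been selected by the breed test in the same libraries, so their unadjusted p values and signs are not independent support. All 16 kept their sign, with a mean size of 0.76 on the log2 scale in both fits that came from moves in both directions, SLC6A9 from 0.42 to 0.21, TMEM138 from 0.57 to 0.79 and ENSSSCG00000008677 from 0.77 to 1.196, and the median SE rose from 0.15 to 0.27. By camera with the preset correlation, the mitochondrial group then had an adjusted p of 0.311 and fatty acid synthesis 0.0146. In the fit without that term, fatty acid synthesis had an adjusted p of 0.173 by camera with an estimated correlation.

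In females alone, no gene passed the test between breeds with edgeR, with 392 genes at an unadjusted p under 0.05, 0 calls with DESeq2 and 3 with limma voom. The genes with the smallest p were all higher in crossbred females, in 5 of 5 animals above the Iberian female median. TRPC4AP, which overlaps MYH7B and is uncertain, had a log2 difference of 1.23 (SE 0.26), SEPTIN1 1.18 (SE 0.26), USP16 1.83 (SE 0.42), TARBP1, which also overlaps a locus, 1.49 (SE 0.35) and DUT 1.04 (SE 0.25), with edgeR adjusted p from 0.239 to 0.271. The mitochondrially encoded group was lower in crossbred females, with 12 of 13 fitted values below 0, a median of -0.16 and an adjusted p of 0.0093 by camera, against an adjusted p of 0.812 with an estimated correlation and 0.689 by fry. Its call was lost in 4 of 20 fits that left out 1 library (adjusted p up to 0.322), and its direction turned with the alignment split as a term (adjusted p = 0.973). That term was estimated from Iberian males alone, so the turn was not measured in females. Without Iberian male replicate 5, which enters the shared estimate of the spread, 8 genes passed. All 5 Iberian females were in the high set and all 5 crossbred females in the low set, so no value within a set could be had.

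In males alone, 2 genes passed between breeds. TBCD was higher in crossbred males, at 41.3 ± 4.84 CPM against 17.1 ± 3.14 (SD, n = 5 each; log2 1.28, SE 0.21, edgeR adjusted p = 0.0085), in 5 of 5 animals above the Iberian male median. GRPEL2, a co-chaperone of mitochondrial protein import that overlaps IL17B, was lower, at 25.8 ± 5.998 against 45.9 ± 5.87 (log2 -0.84, SE 0.16, edgeR adjusted p = 0.0357), in 5 of 5 animals below. The mitochondrially encoded group was lower, with 13 of 13 values below 0, a median of -0.35 and 10 members lower when adjusted over the list alone (camera adjusted p = 8.64e-09, adjusted p = 0.309 with an estimated correlation and 0.0799 by fry). Among low-share libraries only (3 Iberian and 5 crossbred males), TBCD had a log2 difference of 1.17 (SE 0.21, edgeR adjusted p = 0.183) and GRPEL2 -0.74 (SE 0.22, edgeR adjusted p = 0.373), and 1 other gene passed. Without Iberian male replicate 5 there were 7 calls, both genes among them. TBCD lost its call in 4 and GRPEL2 in 14 of the 20 fits that left out 1 library. TBCD also lost it with 2 surrogate variables, and GRPEL2 with the filter at 1 CPM in 5 libraries and with only the 2 groups compared. Both lost it with the alignment split as a term, where TBCD had 1.16 (SE 0.25, edgeR adjusted p = 0.0634) and GRPEL2 -0.76 (SE 0.18, edgeR adjusted p = 0.0744). The mitochondrially encoded group in males kept its camera call with that term (adjusted p = 0.00158, and 0.0236 also without Iberian male replicate 5).

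Between sexes, 5 of 7090 genes passed, 3 higher and 2 lower in males. RBBP7, an X-linked histone-binding protein at 13293278 to 13317074 of chromosome X (ENSSSCG00000012149), was lower in males, at 53.7 ± 6.43 CPM against 82.1 ± 14.5 in females (SD, n = 10 each; log2 -0.60, SE 0.10, edgeR adjusted p = 8.2e-04), in 10 of 10 males below the female median. TXLNG lies 907 bp away, so RBBP7 counts are uncertain. The 4 other calls had no symbol and were each at 0 in every library of 1 sex. ENSSSCG00000032435 was at least 356-fold higher in females, and ENSSSCG00000012178, ENSSSCG00000032661 and ENSSSCG00000012179 were at least 154-fold, 131-fold and 44.2-fold higher in males, against a floor of 3 counts over the group. Of the Y-linked list, EIF1AY had 0 counts in all females and up to 7 in males, and KDM5D 0 and up to 2. XIST had no identifier matched by symbol. No gene list passed between sexes (smallest adjusted p = 0.604, for vessel genes, 8 of 8 above 0 in males).

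Within Iberian animals, HINT3, a histidine triad protein at 1.60 on the log2 scale (SE 0.30, edgeR adjusted p = 0.0140), was higher in males, at 11.8 ± 2.88 CPM against 3.798 ± 0.89 in females (SD, n = 5 each), in 5 of 5 males above the female median. In crossbred animals HINT3 measured 5.37 ± 1.85 CPM in males and 5.43 ± 1.89 in females. It was called neither between sexes over both breeds nor for the interaction. The 4 other Iberian calls were the sex-limited identifiers. Within the 7 high-share Iberian libraries HINT3 had 1.77 (SE 0.36, edgeR adjusted p = 0.0247) and 10 genes passed. HINT3 lost its call with limma voom (adjusted p = 0.0712) and in 4 of 20 fits that left out 1 library (edgeR adjusted p up to 0.103). Within crossbred animals, all of one set, RBBP7 was lower in males (log2 -0.82, SE 0.13, edgeR adjusted p = 0.0014), at 52.1 ± 5.77 against 91.7 ± 12.9, beside the same 4 identifiers. Within Iberian animals RBBP7 measured 55.3 ± 7.28 CPM in males and 72.4 ± 8.46 in females and was not called. With the alignment split as a term RBBP7 had -0.52 between sexes (SE 0.11, edgeR adjusted p = 0.0710).

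For the breed by sex interaction, which asks whether the breed difference differed between males and females, GRPEL2 was the single call (log2 -1.28, SE 0.23, edgeR adjusted p = 0.0268). It measured 29.5 ± 4.28 CPM in Iberian females, 40.2 ± 3.92 in crossbred females, 45.9 ± 5.87 in Iberian males and 25.8 ± 5.998 in crossbred males (SD, n = 5 each). No gene list passed (smallest adjusted p = 0.251, for the mitochondrially encoded list). GRPEL2 lost its call in 13 of the 20 fits that left out 1 library, with the replicate number as a block (-1.28, SE 0.24, edgeR adjusted p = 0.0610) and with the alignment split as a term (-1.40, SE 0.26, edgeR adjusted p = 0.0533), and kept it without Iberian male replicate 5 (-1.33, SE 0.22, edgeR adjusted p = 0.0030).

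**Figure D4:**
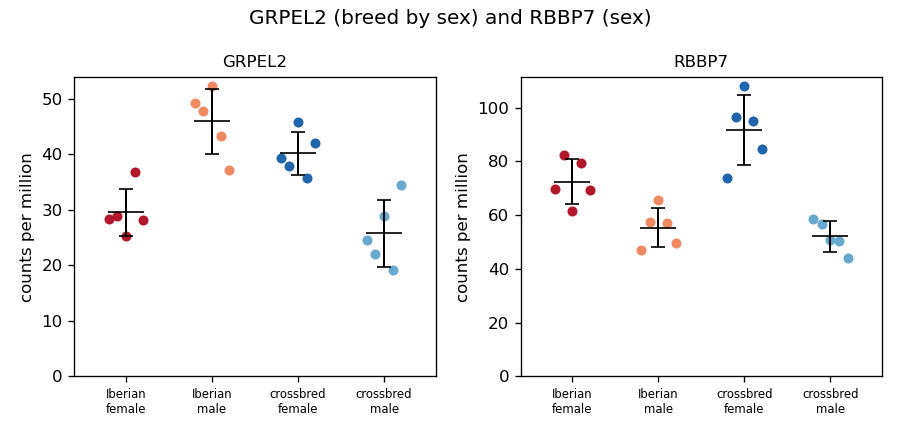
CPM (y axis, from 0) of GRPEL2 and RBBP7 in each library of the 4 groups (x axis), with the group mean and SD as a bar. GRPEL2 is higher in crossbred than Iberian females and lower in crossbred than Iberian males. The mean of RBBP7 is lower in males of both breeds, but within a breed it was called in crossbred animals only.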

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

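Of the tests in this part, that of the alignment split within Iberian males was set before its result was seen; those of ND6, of pituitary RNA, of another tissue and of the counts of other splits were chosen or written down after their results had been seen.

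Among 124 checks of a named gene or a library quantity in a group of 5, 10 had 1 library far from the others, where chance gives about 1 in 20. In Iberian male replicate 5, TMEM138 measured 37.2 CPM against 72.4 to 80.6 in the other Iberian males, CRISP1 2.32 against 8.53 to 11.5, ENSSSCG00000008677 38.7 against 126 to 154, and CPSF7 62.0 against 85.9 to 91.0. SLC6A9 measured 97.4 in Iberian female replicate 1 against 119 to 127. USP16 measured 1.71 in Iberian male replicate 4 against 5.31 to 6.88, and 6.93 in crossbred female replicate 1 against 9.88 to 11.3. GYPC measured 2.51 in crossbred female replicate 5 against 13.004 to 20.3. TMEM138 measured 93.9 in crossbred female replicate 4 against 103 to 105, and 94.8 in crossbred male replicate 5 against 107 to 112. The breed difference of GRPEL2 differed between males and females by -1.28 on the log2 scale in the interaction test.

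The first pattern is the small share of entries assigned to genes, with a median of 82.7% in no feature. ND6 had the most counts of the 13 mitochondrial messengers in 20 of 20 libraries, and its ratio to COX1 had a median of 35.3 and was at least 19.8 in every library. That argues against reads outside annotated exons as the whole cause, since those would leave COX1 above ND6. Of the 100 highest-counted genes with a position, 99 had another gene within 5 kb, against 80.9% of 5463 others (Fisher's exact test, two-sided, p = 3.44e-08). Neighbours on either strand were taken and their counts were not, so this comparison cannot tell one way of counting from another. The ND6 values may be explained by reads assigned to the strand opposite to the gene. That hypothesis needs libraries which mark strand, while the kit named in the labels is not stated to do so. Whether the kit or the counting is at issue stays open, and no biological explanation was tested.

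The second pattern is Iberian male replicate 5, where PRL, CGA and FSHB had 157, 163 and 111 counts, and 3 of 3 had at least 10 times the count of every other library. Of the anterior pituitary list, fixed before the data were examined, 10 of 15 members had an identifier and 8 of these were higher there than in every other library, but TSHB, TBX19 and GHRHR only with 2 counts against at most 1, and POU1F1 was not higher, with 1 count against up to 5. CHGB had 1448 counts against a mean of 171, and RUVBL2, 82 bp from LHB, 26861 against a mean of 209, and ND6 took 23.7% of the gene counts there. Another tissue in place of hypothalamus is argued against by the markers of neurons, astrocytes and myelin, whose median log2 difference from the other Iberian males was -0.11 over 44 genes (quartiles -0.60 to 0.40), though this joined neurons at 0.51 (10 of 13 above 0) with myelin at -0.58 (2 of 18 above 0), and HCRT had 3 counts against 7 to 32 elsewhere and PMCH 0 against 3 to 16. Pituitary RNA mixed into that library may therefore account for it, and a difference of that animal itself stays open as untested.

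The third pattern is the breed calls beside the share of low-quality alignments, whose median was 5.57% in 7 Iberian libraries. Within Iberian males, the 2 high-share and 3 low-share libraries differed on the 16 called genes by a mean of -0.0178 on the log2 scale, signed by breed, with -0.13 to 0.14 for the others of the 10 splits and 0.04 without replicate 5, where the mean breed difference was 0.76. So within Iberian males these genes did not follow the split. They were called in these same libraries, however, which favours genes with a small spread within a group. In females the split and breed coincide, so the test cannot exclude a batch along this split. The end of all calls with the split as a term came with folds of the same mean size, some smaller and some larger. The median SE was then 0.27 in place of 0.15. That term was estimated from Iberian males alone, the only group with libraries of both sets. The unchanged mean size therefore repeats the difference within them and is no further support. Pituitary RNA is argued against as the cause, since 14 of the 16 genes stayed called without that library. Breed, a batch along this split and another batch that follows breed may each account for the calls and stay open.

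Other splits of the same libraries were drawn 100 times, the real one included. Breed had 16 calls (1 split as large, at most 1 call in another) and breed in males 2 calls (1 split, at most 1). Both counts were larger than in every other split drawn. There were 5 calls for sex (1 split, at most 1), sex in Iberian (1 split, at most 2) and sex in crossbred (2 splits, at most 6). The sex calls other than RBBP7 and HINT3 were at 0 in every library of 1 sex. Those counts had to stand out and cannot test chance. The interaction had 1 call (3 splits, at most 2), too few to exclude chance. All these contrasts fell under a limit of 5 in 100. That limit was written down after the results were seen and was not adjusted over the 7 contrasts. For breed in females there was nothing to compare, with 0 calls in 100 of 100 splits.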

How the results depend on the processing

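The alternatives named for alignment share were chosen after the data were seen; the cause of the changes below was not tested unless stated. Breed called 16 genes, 78 with no filter on low counts (19471 genes tested), 48 with 2 surrogate variables, 0 with the low-quality share as a term and 1 with that term and without 1 library. The first surrogate variable was 0.96 in Iberian male replicate 5 and -0.13 to 0.03 elsewhere, so that setting was not independent of leaving this library out. Breed in females called 0, and 3 with limma voom, 17 with no filter, 11 with surrogate variables and 4 with only the groups compared. Breed in males called 2, and 16 with DESeq2, 9 with voom, 48 with no filter and 1 at 1 CPM in 5 libraries. The DESeq2 count was adjusted over 3230 genes only, against 7090 in the main fit. Breed in males called 0 with the share as a term, 4 with that term without 1 library and 1 in low-share libraries. Sex called 5, and 9 with DESeq2, 12 with no filter and 9 at 1 CPM. Sex in Iberian called 5, and 8, 12 and 8 under the same settings and 10 in high-share libraries. Sex in crossbred called 5, and 8, 12 and 8. The interaction called 1, and 7 with no filter, 0 with the replicate block and 0 with the share as a term. HCRT turned to -0.0253 with surrogate variables and to -0.12 with the share as a term without 1 library, its SE being 0.19 and 0.36. The mitochondrial list in females turned direction with the share as a term (camera adjusted p = 0.973, and 0.867 without 1 library). Iberian males alone set that term, so the turn was not measured in females. Leaving out each library gave 2 (without crossbred female replicate 4) to 23 (without Iberian male replicate 5) calls for breed, 0 to 8 for breed in females, 0 to 7 in males, 5 to 6 for sex, 4 to 6 for sex in Iberian, 5 for sex in crossbred and 0 to 1 for the interaction. TBCD and TMEM138 kept their breed call in all 20 of these fits, and GYPC lost it in 16, SGCA in 15 and WDR45B in 17. The replicate block gave 15 breed calls, 13 of them shared. Same-numbered libraries correlated at a mean of 0.03 (-0.08 to 0.19) and 5 of 30 pairs exceeded 0.1, against a mean of -0.00759 and 7 of 120 pairs for different numbers. Among 20 libraries 7 correlated best with their own number, so whether the numbers pair the animals weakly stays open. Counts of 1430138 to 2384615 per library limit genes near the filter.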

Other observations

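Of the tests in this part, that of a breed difference shared by the sexes was set before its result was seen; those of positions, X-linked genes and peptide pairs were chosen after the data had been seen.

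Counts assigned to vasopressin and oxytocin, peptides made in the same hypothalamic nuclei, varied together over the 20 animals. AVP overlaps a locus without a gene symbol, OXT was at 0 in 7 libraries, and the strand of the counts is uncertain. Whether the messengers themselves varied together is therefore not settled. The log2 CPM of AVP (5 to 55 counts) and OXT (0 to 17 counts) had a Pearson r of 0.68 (permutation p = 0.0013, adjusted p = 0.0026 over 2 relations) and a Spearman rho of 0.67 (permutation p = 0.0020, adjusted p = 0.0040). Without the 2 animals farthest from the AVP median r was 0.57, and it was 0.65 within the 13 low-share and 0.72 within the 7 high-share libraries. For HCRT and PMCH, made in the lateral hypothalamus, r was 0.55 (permutation p = 0.018, adjusted p = 0.018) and rho 0.29 (permutation p = 0.209, adjusted p = 0.209). Their r fell to 0.27 without the 2 farthest animals and was 0.16 without Iberian male replicate 5, so this relation rests on those animals. It was 0.70 within the low-share and 0.18 within the high-share libraries.

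Of 141 tested X-linked genes, 79 were fitted higher and 62 lower in males, with a median log2 difference of 0.03 against 0.01 for all others. RBBP7 was the 1 call over all genes, and EMD passed beside it when adjusted over the X-linked genes alone. Without Iberian male replicate 5, 9 genes were called between breeds that had not been before. Among them LSS, an enzyme of cholesterol synthesis, measured 0.89 on the log2 scale (SE 0.20), the calcium channel ITPR1 0.73 (SE 0.16), TMEM9B 0.53 (SE 0.09) and SMAP1 -0.33 (SE 0.06).

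Some genes called between breeds lay near each other. Of the 12 called genes with a position, 2 pairs had starts within 1 Mb, CPSF7 with TMEM138 (47.3 kb apart) and WDR45B with TBCD (196 kb apart), and 95 of 10000 random sets of 12 tested genes held as many (permutation test by random draws, p = 0.0096). The test rests on these 2 pairs, and WDR45B, at an edgeR adjusted p of 0.0490, lost its call in 17 of 20 fits that left out 1 library, with the replicate block and without robust estimation. Stretches of the genome that differ between the breeds are a possible explanation that the counts alone do not test.

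A breed difference shared by females and males across many genes was not seen. The correlation of the 2 differences across 7090 genes, which are not independent replicates, was 0.0633, with -0.23 to 0.26 over other splits of the animals within sex, and 14 of 100 splits were as large. The 16 called genes had the same sign in both sexes in 16 of 16 cases, but they were selected for their mean over the sexes.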
